A study of Mus musculus with 4 samples.

How the data were processed

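Cells negative for CD45 and CD31 were sorted from the lungs of tamoxifen-dosed mice of about 8 weeks, carrying Gli1-CreERT2 and the Rosa26 mTmG reporter, and profiled by droplet 3′ RNA sequencing. The labels name the kit version as 3 and the series design as 3.1, and the labels also give different strains in different fields, so no strain is stated here. The 4 samples have the same labels and form 1 group. The matrix has 1 barcode suffix, the 4 sample entries of the demultiplexing file share 1 description and 1 second index over 4 lanes, and no file used here maps cells to samples. All cells were therefore treated as 1 sample. The samples had 69050962, 74007731, 65156149 and 74901791 reads passing filter, 283116633 in total, and none stood apart at either end (larger gap of the highest or lowest sample to its neighbour 0.400 of the range).

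Per the submitters' processing notes, the authors used Cell Ranger 3.0.0 with build mm10, and the deposited matrix holds raw UMI counts per gene and barcode, 85746975 UMIs in 11118 barcodes and 31055 features, among them the added sequences Egfp and TdTomato. The deposited run summary gives 25464 mean reads per cell, a sequencing saturation of 51.0%, 92.4% of reads in cells and medians of 7325 UMIs and 2484 genes. Per the file headers, the authors' deposited cluster table gives for each of 17 clusters a mean count per cell, a log2 fold change and an adjusted p-value. The clustering, the test, the scaling of the mean counts and the comparison set behind those columns are not given in the sources used here. The annotation release is not given either. Coordinates are from GENCODE M21 on mm10, and 16 of 16 hedgehog genes were found there by gene identifier.

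Barcodes with at least 500 genes and at most 10% mitochondrial UMIs were kept, which left 9391. The filter found 1296 barcodes under the gene minimum and 1545 over the mitochondrial maximum. Scrublet in scanpy (expected rate 0.08) called 458 doublets (4.88%), and after their removal 8933 cells remained, with 699 to 77372 UMIs each. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were chosen after leaving out programme, mitochondrial, ribosomal and reporter genes, and 30 principal components, a shared graph of 15 nearest neighbours and Leiden clustering at resolution 1 (seed 0) gave 25 clusters. Programme genes thus did not define the clusters, though they can be correlated with genes that did. Tools were Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0, scikit-image 0.26.0 and matplotlib 3.10.9.

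A cluster was named X-like by the highest mean z-score over 19 marker lists, given at least 3 list markers with a UMI in 25% of its cells, and stayed unnamed where genes of another type led it. The rule as first written compared all lists, including those with under 3 detected markers, and then left 7 rather than 4 clusters unnamed. The change was made after the data were examined, and the first form was kept as an alternative. No cluster was named pericyte-like, basal, neuroendocrine, endothelial, glial, erythroid or chondrocyte-like. The marker lists, 14 programme lists with 221 genes, the comparisons and the rule for named genes were fixed before the data were examined.

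For each class or set of cells, counts were summed and given as CPM with exact Poisson 95% intervals. Ratios of CPM have exact conditional binomial intervals and shares have Clopper-Pearson intervals, and all of them cover counting error only. With 1 sample there was no test, and no p-value was computed from cells. A gene with no UMI in a set of cells was compared with a floor of 3 UMIs over the set. For shares of cells with a UMI, each cell was also thinned to 2000 UMIs, and shallower cells were left out. List members with at least 30 UMIs over both sets were counted at ratios of 2 or more and 0.5 or less, leaving out genes that named the class compared, and medians were ranked among 10000 random lists matched on mean level. Mesenchymal cells with a Gli1 UMI were each matched, deepest first, to the 5 unused cells of their cluster without one that were nearest in total UMIs. This ran out of unused cells in adventitial-like clusters, so 636 of 875 were matched, 560 of 799 in adventitial-like cells and all in the other classes, and median depths still differed (10524 against 8441 UMIs). Reporter-high cells had 1000 CPM or more of Egfp and reporter-low cells under 200 CPM, matched 1 to 1 by cluster and total UMIs. The reporter comparisons and those between adventitial-like clusters were added after the data were examined.

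Named genes, some of which are not reported here, were taken from the hedgehog list, the 12 highest and 12 lowest programme genes with at least 100 UMIs between adventitial-like and alveolar-like cells, and for matched cells the 12 highest and 12 lowest of all genes with at least 100 UMIs and 50 CPM, outside mitochondrial, ribosomal and model gene names, with hedgehog and lung transcription factor genes added. Further named genes were the 5 highest and 3 lowest programme genes of each other mesenchymal class, up to 4 markers per class, and the 3 largest log2 fold changes per mesenchymal-matched cluster of the authors' deposited table, at an adjusted p of 0.05 and a mean count of at least 1. The deposited clusters were set beside those made here by Spearman correlation of mean counts over 20473 genes.

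The ratio step was run on simulated Poisson counts, drawn for whole sets of cells with no variation between cells. The intervals assume such counts, so the coverage below checks the calculation and does not show that the intervals hold for real cells. For adventitial-like against alveolar-like cells over 12635 genes, a true ratio of 4 in 50 genes was found at 2 or more in 100% and covered by the interval in 92%. A true ratio of 0.25 in 45 genes was found at 0.5 or less in 100% and covered in 97.8%. Of the 12440 unchanged genes there, 0.402% reached 2 and 0.129% fell to 0.5, at a coverage of 95.7%. For the matched cells over 12366 genes, true ratios of 4 and 0.25 were recovered in 100%, and 0.140% and 0.584% of 12166 unchanged genes passed the upper and lower limit. Alternatives covered looser and stricter cell filters, doublets kept, 4000 variable genes, resolutions of 0.5 and 2.0, splitting the UMIs into separate parts for clustering and values, other ways of summing, other thinning depths and other matching. Alternatives added later were another seed, the first naming rule, leaving out clusters 6 or 15, matching within adventitial-like cells only and other reporter limits. Reads were not used here.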

Results

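Transcripts were counted in single cells sorted from mouse lung as negative for CD45, a leukocyte surface protein, and for CD31, an endothelial surface protein. The mice were about 8 weeks old, had received tamoxifen, and carried 1 copy of a tamoxifen-activated Cre recombinase at the Gli1 locus and 1 copy of the mTmG reporter at Rosa26, which makes membrane tdTomato before recombination and membrane EGFP after it. Gli1 is a transcription factor and target gene of hedgehog signalling, so such a cross marks cells that expressed Gli1 around dosing. The 4 samples bear the same labels and form 1 group, and their reads, 65156149 to 74901791 per sample, were pooled in a single deposited matrix in which no barcode names a sample. The matrix therefore counts as 1 sample with no replicates, no test between cells was made, and all intervals are 95% intervals that cover counting error only. It holds 11118 barcodes, which equals the cell number given with the series, and 8933 cells with 76127432 unique molecular identifiers (UMIs) were kept, at a median of 7967 UMIs and 2610 genes per cell.

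The sorted cells were mostly fibroblasts, with a sizeable epithelial share. Adventitial-like fibroblasts, led by Dcn (10556 CPM, from UMIs summed over the class), Clec3b, Mfap5 and Pi16, made up 42.0% of kept cells (3753 cells, exact binomial interval 41.0 to 43.0%). Alveolar-like fibroblasts, led by Inmt (5600 CPM), Mfap4, Npnt and Limch1, made up 20.6% (1837 cells, 19.7 to 21.4%). Smaller mesenchymal groups were a cluster of 424 peribronchial or myofibroblast-like cells (4.75%, led by Hhip, Mustn1, Aspn and Enpp2), 221 smooth muscle-like cells (2.47%, led by Acta2, Tagln, Myh11 and Des) and 209 mesothelial-like cells (2.34%, led by Msln at 3943 CPM and Upk3b at 2987 CPM). Epithelial cells summed to 24.1%, of which 1626 were alveolar type 2-like (18.2%), with Sftpc, the surfactant protein C gene, at 192790 CPM. There were 223 ciliated-like cells (Tppp3 at 3176 CPM), 214 alveolar type 1-like cells (Ager at 15153 CPM and Hopx at 8949 CPM) and 87 club or secretory-like cells, with Scgb1a1, the club cell secretory protein gene, at 509220 CPM. Mesenchymal classes together reached 72.1% (71.2 to 73.1%). Leukocyte-like cells, which the sort should remove, made up 1.02% (91 cells, 0.821 to 1.25%, led by S100a8 at 4452 CPM), and Ptprc, which encodes CD45, had a UMI in 0.817% of kept cells. Pecam1, which encodes CD31, had a UMI in 2.34% of kept cells and in 88.5% of the 61 cells of an unnamed cluster with endothelial and haemoglobin genes. Pecam1 also had a UMI in 17.2% of smooth muscle-like cells (38 of 221, 12.5 to 22.8%), against 1.77% of all mesenchymal cells. Where this RNA came from was not tested. The shares depend on the sort and on recovery from tissue, 248 cells in 4 clusters stayed unnamed, and smooth muscle-like was a near tie with pericyte-like (mean marker z-scores of 2.78 and 2.60). The share of all named classes that the sort should remove, leukocyte-like cells alone in the main run, was 1.91% with the looser cell filter and 1.67% with clusters and values from separate parts of the UMIs.

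Gli1 UMIs were concentrated in adventitial-like fibroblasts. Gli1 (chromosome 10, 127329882 to 127341974, minus strand, build mm10) reached 27.4 CPM in that class (929 UMIs, exact Poisson interval 25.7 to 29.3). The level was 5.06 CPM in alveolar-like (3.75 to 6.66), 6.82 in peribronchial or myofibroblast-like (3.53 to 11.9), 6.19 in smooth muscle-like (3.09 to 11.1) and 5.37 in mesothelial-like cells (2.57 to 9.87). The adventitial-like level was 5.06-fold that of all other mesenchymal cells (4.04 to 6.41). Of the 875 mesenchymal cells with a Gli1 UMI, 799 were adventitial-like (91.3%). Within the adventitial-like class the level ran from 33.1 CPM in cluster 3 (28.7 to 38.0) to 17.6 CPM in cluster 6 (14.1 to 21.7). Within the alveolar-like class it was 6.29 CPM in cluster 2 and 1.39 CPM in cluster 7 (4 UMIs).

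Per cell, 21.3% of adventitial-like cells had a Gli1 UMI at a median of 8750 UMIs, and 5.24% (4.55 to 6.00%) had after each cell was thinned to 2000 UMIs. Among alveolar-like cells the share was 0.936% (0.536 to 1.52%), and 2.67% before thinning, at a median of 5001. Alveolar type 2-like cells, which should lack Gli1, gave 1 UMI in 1626 cells at a median of 9380 UMIs and 0 of 1618 after thinning, which allows a share of up to 0.228% (exact upper bound). Other cells that should lack Gli1 were less clear. Ciliated-like cells had 1.46 CPM (4 UMIs, 0.398 to 3.74) and leukocyte-like cells 4.07 CPM (3 UMIs, 0.840 to 11.9). Unnamed cluster 22, with endothelial genes, had 0 UMIs, which allows up to 8.95 CPM. The leukocyte-like interval overlaps those of the mesenchymal classes other than adventitial-like. Thinning left out 13 adventitial-like, 128 alveolar-like and 8 alveolar type 2-like cells. At the finer clustering resolution of 2.0 the adventitial-like ratio of 5.06 was 2.73, and the smooth muscle-like ratio of 0.293 ran from 0.0355 to 0.874 over the alternatives.

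**Figure D1:**
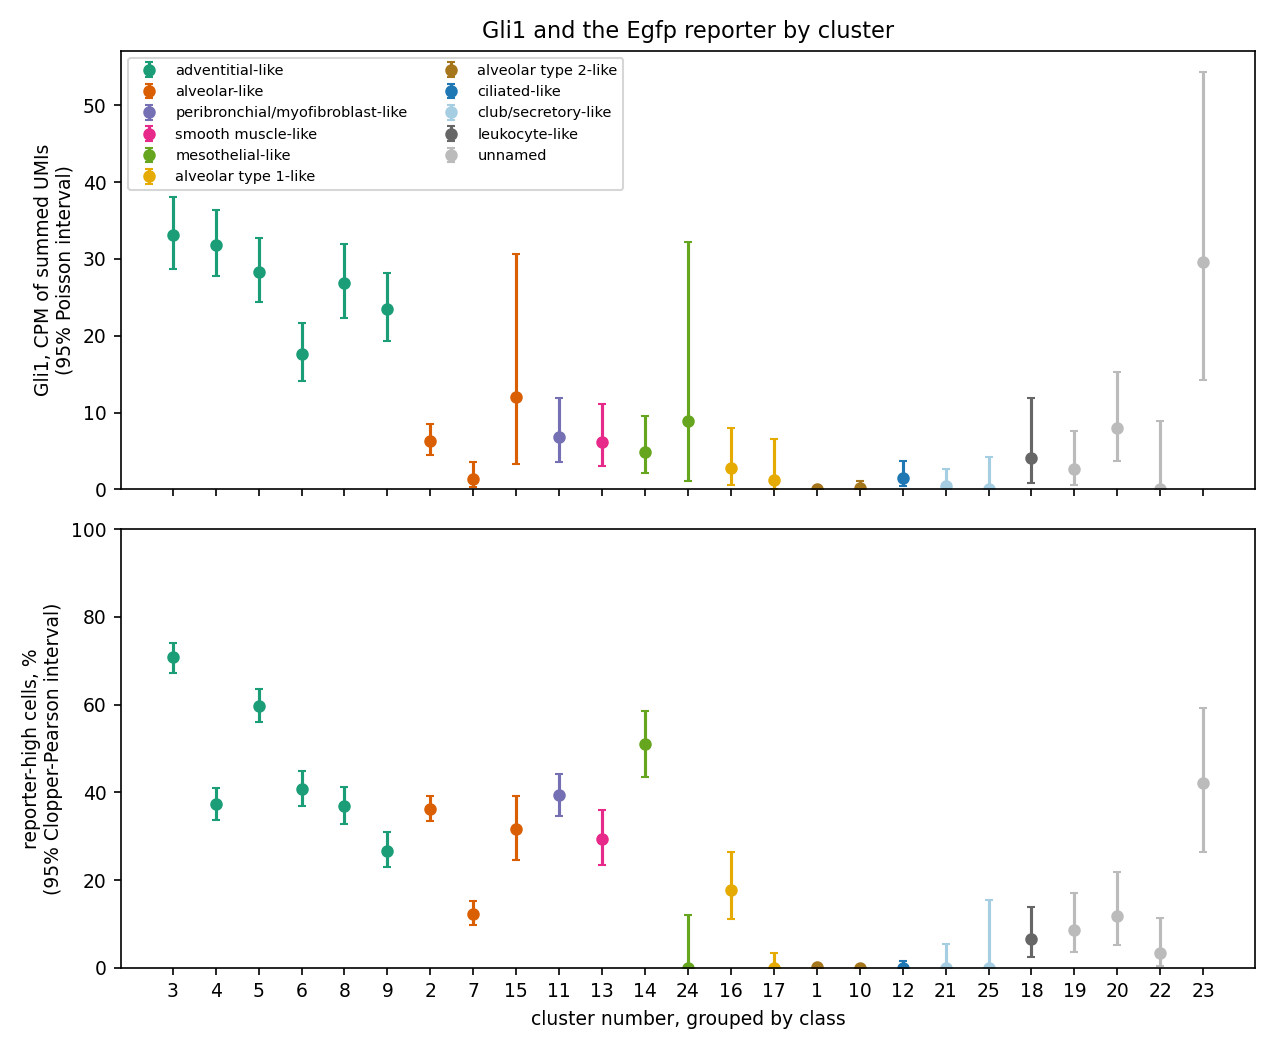
Gli1 level in CPM of summed UMIs (top, points with exact Poisson 95% intervals) and share of reporter-high cells in percent (bottom, points with exact binomial 95% intervals) for each of the 25 clusters, coloured by class; intervals cover counting error only. The 6 adventitial-like clusters sit between 17.6 and 33.1 CPM, while reporter-high cells are also frequent in alveolar-like cluster 2 (36.2%), in cluster 11 (39.4%) and in mesothelial-like cluster 14 (51.1%).

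Other hedgehog pathway genes did not all follow Gli1. Ptch1 (chromosome 13, 63508328 to 63573598), which encodes the hedgehog receptor and is itself a target gene, was 206 CPM in adventitial-like, 121 in peribronchial or myofibroblast-like, 90.7 in mesothelial-like and 85.2 in alveolar-like cells. It was 2.46-fold higher in adventitial-like than in other mesenchymal cells (2.31 to 2.61). Within the adventitial-like class Ptch1 ran from 388 CPM in cluster 3 (372 to 403) to 56.4 CPM in cluster 9 (49.9 to 63.5). Cluster 3 had mean marker z-scores of 0.865 for adventitial and 0.475 for alveolar fibroblasts, and the ratio without it was not computed. Foxl1 (21.8 CPM, 6.06-fold) was also highest in adventitial-like cells among the named classes, and Cdon, a co-receptor gene, was 2.79-fold higher there than in other mesenchymal cells. Alveolar type 1-like cells also had Ptch1, at 89.1 CPM (76.3 to 103), with 96.2 CPM in cluster 17, the one of their clusters with little fibroblast RNA. Of the measured list members, 5 of 13 were at least 2-fold higher and 1 at most 0.5-fold in adventitial-like over other mesenchymal cells. That 1 was Hhip (chromosome 8, 79965851 to 80058006), a hedgehog-binding inhibitor and target gene, which reached 4535 CPM in the peribronchial or myofibroblast-like cluster against 147 in adventitial-like and 37.6 in alveolar-like cells, but it also served to name that cluster. Among the named classes, the same cluster had the highest Foxf1 (208 CPM against 64.6 in adventitial-like cells), a lung mesenchyme transcription factor. Mesothelial-like cells instead had the highest levels in a named class of the signal transducer gene Smo (275 CPM against 52.5 in adventitial-like), Gas1 (1183 against 389) and Cdon (194 against 98.7). Gli2 was 11.4 CPM in adventitial-like and 10.1 in alveolar-like cells, Gli3 15.1 and 11.5, Boc 146 and 89.6, and Sufu 14.7 and 9.61.

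The ligand gene Shh (chromosome 5, 28456815 to 28467256) was found in epithelium, with 241 UMIs in epithelial cells (10.4 CPM, 9.10 to 11.8) against 4 in mesenchymal cells (0.0814 CPM, 0.0222 to 0.208). Its UMIs were spread over alveolar type 2-like (147), club or secretory-like (35), ciliated-like (31) and alveolar type 1-like cells (28). These counts do not rank the classes by level, since the classes differ in size, from 1626 alveolar type 2-like to 87 club or secretory-like cells. Ihh had 15 epithelial UMIs, 9 of them in ciliated-like cells, and 5 mesenchymal UMIs, and Dhh had 4 and 9, too few to rank classes. For Gas1, the ratio of 1.03 for adventitial-like over other mesenchymal cells fell below 1 in several alternatives, for example 0.802 with clusters and values from separate parts of the UMIs. At resolution 2.0, 3 rather than 5 list members were at least 2-fold higher, with Ptch1 at 1.06 and Foxl1 at 1.31.

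Adventitial-like and alveolar-like fibroblasts differed across most programmes, and none of the programme genes took part in the clustering. Higher in adventitial-like cells were the surface protein genes Thy1 (129-fold, 23.0 to 5089, on 1 UMI in alveolar-like cells), Ly6a (53.5-fold, 46.2 to 62.2) and the retinoic acid synthesis gene Aldh1a2 (107-fold, 45.6 to 329). So were the activin antagonist gene Fst (69.7-fold, 37.8 to 145) and the cytokine gene Il33 (37.6-fold, 25.2 to 58.8). Matrix genes with high ratios were Col8a1 (85.6-fold, 15.2 to 3393, also on 1 UMI), the proteoglycan gene Lum (59.9-fold, 636 against 10.6 CPM), Emilin2 (27.5-fold), Fbln2 (19.9-fold), Col15a1 (19.0-fold) and the hyaluronan synthase gene Has2 (17.5-fold). Wnt2b, with no UMI in alveolar-like cells, was at least 11.6-fold higher in adventitial-like cells against a floor of 3 UMIs over the class. Lower in adventitial-like cells were the adhesive matrix gene Tnc (ratio 0.0322, 0.0263 to 0.0390), Wnt2 (0.0833) and the retinoid genes Aldh1a1 (0.142) and Lrat (0.157). Further low genes were the contractile genes Tagln (0.164) and Des (0.203), the transcription factor gene Foxf2 (0.184), the KIT ligand gene Kitl (0.232), the lipid droplet gene Plin2 (0.235) and the complement gene C7 (0.242). Fgfr4 (0.0505) and Itga8 (0.136) were also among the lowest, but helped to name the alveolar-like class.

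By list, 6 of 13 hedgehog genes were at least 2-fold higher in adventitial-like cells and 0 were at most 0.5-fold, with a median ratio of 1.79. The Wnt list had 10 of 19 higher and 2 lower, chemokines, cytokines and complement 9 of 17 and 2, the BMP and TGF-beta list 8 of 19 and 2, and proteoglycans 6 of 12 and 1. The counts were 6 of 17 and 1 for collagens, 7 of 21 and 1 for elastic fibre and adhesive matrix, and 4 of 9 and 2 for stromal progenitor surface genes. Lists with medians below 1 were the FGF and HGF list (2 of 13 higher, 3 lower, median ratio 0.598) and the PDGF and KIT list (2 of 9 and 4, 0.520). Medians were also below 1 for lung mesenchyme transcription factors (4 of 17 and 5, 0.832), lipid and retinoid genes (4 of 13 and 4, 0.889) and immediate early and heat shock genes (1 of 15 and 0, 0.831). The contractile list had 1 of 10 higher, 2 lower and a median ratio of 1.08. In total, 70 programme genes were at least 2-fold higher and 29 at most 0.5-fold. Hedgehog was not alone in this: its median and those of the Wnt list and of chemokines, cytokines and complement lay at percentile 100 among 10000 random lists matched on mean level, those of 5 further lists at 99.8 to 99.99, the FGF and HGF median at 0.02 and the PDGF and KIT median at 0, which describes this library only. Alveolar-like cluster 15 was shallow (median 1734 UMIs), and adventitial-like cluster 6 was a near tie between both fibroblast marker lists (mean z-scores of 0.731 and 0.690). Some large folds were smaller in alternatives: with doublets kept Aldh1a2 was 9.20-fold, Fst 9.16-fold, Il33 9.21-fold, Ly6a 10.2-fold, Lum 13.4-fold and Thy1 25.8-fold.

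**Figure D2:**
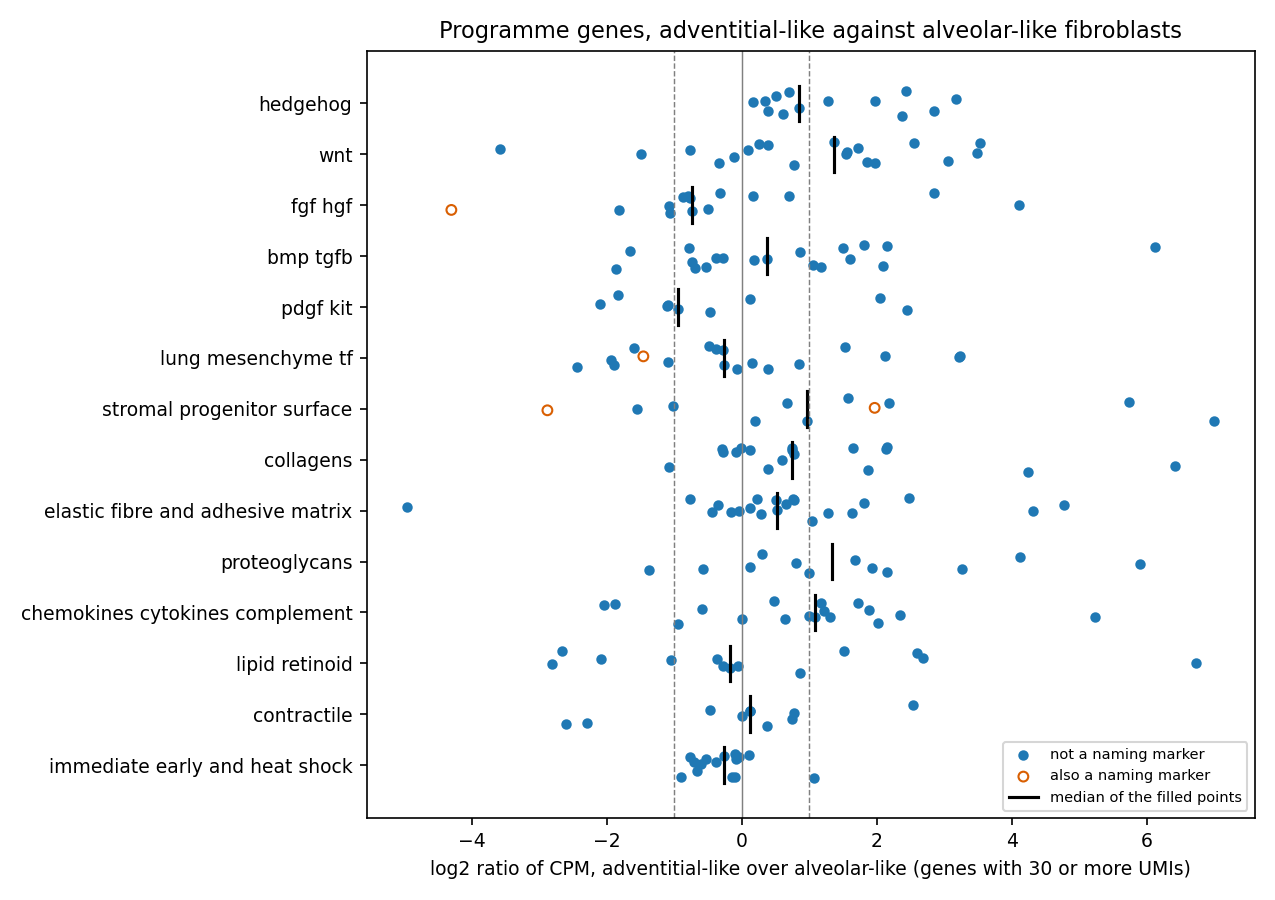
Each point is a programme gene with 30 or more UMIs over both classes, placed by the log2 ratio of CPM in adventitial-like over alveolar-like fibroblasts (horizontal axis) and by its list (vertical axis, with random vertical spread); open circles helped to name a class, black bars are medians of the filled points and dashed lines mark ratios of 2 and 0.5. Hedgehog genes have a median ratio of 1.79, while the PDGF and KIT list has a median ratio of 0.520.

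The smaller mesenchymal classes had distinct programmes. The peribronchial or myofibroblast-like cluster was contractile: all 10 contractile list genes were at least 2-fold above other mesenchymal cells, among them the intermediate filament gene Des (19.8-fold), Cnn1 (15.5-fold) and Actg2 (15.2-fold). Its highest programme genes were Hhip (39.1-fold) and the growth factor gene Fgf18 (39.0-fold), both also naming markers, and its lowest were Ly6a (ratio 0.00564), C7 (0.00582) and Hgf (0.0119), the C7 and Hgf values each resting on 1 UMI. Smooth muscle-like cells had Mcam, an adhesion protein gene, at 124-fold (99.2 to 157) and the naming markers Myh11 (89.2-fold), Acta2 (70.0-fold), Lmod1 (48.3-fold) and Actg2 (42.6-fold), while 0 of 13 hedgehog genes were at least 2-fold higher and 9 were at most 0.5-fold. Lowest there were C7 (0.0404), Hhip (0.0596) and Col23a1 (0.0694). Mesothelial-like cells had the Wnt modulator gene Sfrp2 at 93.7-fold (83.8 to 105), Rspo1 at 72.2-fold (a naming marker), Aldh1a2 at 15.8-fold, Fgf1 at 14.6-fold and Fgf9 at 13.4-fold, and low Myh11 (0.00886, 2 UMIs), Il6 (0.00897) and Ly6a (0.0137). The line between both contractile classes was not firm: in 5 alternatives the Hhip ratio of the smooth muscle-like class was between 1.72 and 6.70, and at resolution 2.0 Cnn1 in the peribronchial or myofibroblast-like class was at 0.520 and Des at 3.29. With doublets kept, Fgf1 in mesothelial-like cells was at 1.53 and Sfrp2 at 274-fold.

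Matched by cluster and pooled over clusters, cells with a Gli1 UMI had slightly more of the hedgehog target transcripts Ptch1 and Hhip, but Hhip reversed in 2 alternatives. The comparison set 636 of the 875 mesenchymal cells with a Gli1 UMI against 3180 cells without, and the rest, all adventitial-like, found no unused match. Depth was not fully matched, at a median of 10524 UMIs with and 8441 without a Gli1 UMI. The gap lay in adventitial-like cells (10688 against 8609), while alveolar-like medians were alike (6630 and 6625). The classes therefore weigh differently in the pooled sets, and whether this shaped the ratios below was not tested. Ptch1 was 1.18-fold (1.12 to 1.25) and Hhip 1.17-fold (1.10 to 1.24), Boc 1.09-fold (1.02 to 1.17), while Gas1 was at 0.945 (0.905 to 0.986) and the intervals of Gli2, Gli3, Smo, Sufu, Cdon, Foxf1 and Foxl1 included 1. The 12 measured hedgehog genes had a median ratio of 1.09. The highest ratios were those of the Wnt modulator gene Sfrp4 (1.51, 1.37 to 1.68), Itih5 (1.37), Hspb8 (1.35) and the matrix genes Fbln2 (1.34) and Vcan (1.31), then Efna5 (1.30), Akap12 (1.29), Erf (1.28), Emilin2 (1.27), Pxdc1 (1.27), Tubb2b (1.26) and Egr3 (1.26). The lowest were Slpi (0.182), Acta2 (0.431), Tagln (0.584), Cdo1 (0.627), Ccl2 (0.640), Ces1d (0.643), Tpm2 (0.702), Upk3b (0.706), Cwc25 (0.733), Npnt (0.734), Cpe (0.738) and Igfbp3 (0.753). Of the lung mesenchyme transcription factors, 0 of 18 were at least 2-fold or at most 0.5-fold, with Hoxa5 at 0.853 (0.779 to 0.933) and Tbx2 at 0.904 (0.818 to 0.997). Of the contractile genes, 6 of 10 were at most 0.5-fold over all classes, a count not made without smooth muscle-like cells, and 1 each of the Wnt, collagen and stromal progenitor surface lists was, while the other 10 lists had none.

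The low Acta2 ratio rested largely on few smooth muscle-like cells. Acta2 was 58.7 CPM with and 76.7 CPM without a Gli1 UMI among the 560 adventitial-like cells and their matches, whereas 6 smooth muscle-like cells with a Gli1 UMI had 4316 CPM against 16275 CPM in their 30 matches. In adventitial-like cells alone Tagln was at 1.12, Tpm2 at 1.01, Upk3b at 4.26 and Slpi at 0.887. With 1 matched cell Ptch1 was at 1.16 (1.08 to 1.23), Hhip at 1.12 (1.05 to 1.20), Egr3 at 0.966, Slpi at 1.47 and Tbx2 at 1.08. Without matching Hhip was at 0.689 and Ptch1 at 1.45. With 2 or more Gli1 UMIs Hhip was at 0.944, Ptch1 at 1.02, Ccl2 at 1.81 and Slpi at 1.40. A cell without a Gli1 UMI may still express the gene.

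The feature list held both reporter transcripts, and the comparisons on them were added after the data were examined. Reporter-high cells, with 1000 CPM of Egfp or more, made up 46.9% of adventitial-like cells (45.3 to 48.5%), 28.2% of alveolar-like (26.1 to 30.3%), 39.4% of peribronchial or myofibroblast-like, 29.4% of smooth muscle-like and 44.0% of mesothelial-like cells (37.2 to 51.0%), the latter with 51.1% in cluster 14 and 0 of 29 in cluster 24. The share among alveolar type 2-like cells was 0.0615% (1 of 1626), and 0 of 223 ciliated-like cells, which allows up to 1.64%, and 0 of 87 club or secretory-like cells were reporter-high. Leukocyte-like cells were reporter-high in 6.59% (6 of 91, 2.46 to 13.8%). Adventitial-like clusters ranged from 70.8% in cluster 3 (67.3 to 74.1%) to 26.7% in cluster 9 (22.9 to 30.9%), and alveolar-like cluster 2 had 36.2% against 12.2% in cluster 7. Alveolar type 1-like cluster 16 had 17.8% and cluster 17 had 0 of 107, and cluster 16 also held fibroblast transcripts such as Inmt at 2371 CPM against 116 CPM in cluster 17. TdTomato was sparse in every class, at 59.0 CPM in alveolar-like cells without an Egfp UMI and 7.88 CPM in such adventitial-like cells. Near the threshold, between 500 and 2000 CPM, lay 21.3% of adventitial-like and 6.70% of alveolar-like cells.

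Gli1 did not differ detectably at this depth between reporter-high and matched reporter-low cells, while Ptch1 was higher in the former. In 1963 cells of each kind, matched on cluster and depth, the Gli1 ratio was 0.970 (0.821 to 1.15). Ptch1 was 1.26-fold higher (1.19 to 1.34), Foxl1 1.43-fold (1.18 to 1.74), Foxf1 1.21-fold (1.10 to 1.33) and Osr2 1.30-fold (1.06 to 1.60), while Cdon was at 0.899 and Hhip at 0.940 (0.902 to 0.979), or 1.02 with doublets kept or the looser filter. The lowest were Enpp2 (0.745), Ifi27l2a (0.755), Sfrp2 (0.766), AW112010 (0.767), Ces1d (0.776), Lbp (0.784), the complement gene C3 (0.789, 1332 against 1688 CPM), Svep1 (0.791), the protease inhibitor gene Serpina3n (0.794), Lgals3bp (0.797), Sned1 (0.802) and the complement factor gene Cfb (0.805). The highest were Sftpb (1.45), Sftpa1 (1.42), Adh7 (1.37), Setd5 (1.36), Smoc2 (1.34), Lyz2 (1.31), Actg2 (1.31), Actc1 (1.29), Myh11 (1.27), Twist2 (1.27) and Apod (1.25). In the peribronchial or myofibroblast-like cluster Ptch1 was 5.27-fold higher in reporter-high than in reporter-low cells (3.57 to 8.00), at 225 against 42.7 CPM, while Hhip was at 0.781. In adventitial-like clusters 3, 4, 5 and 8, not matched on depth, Hhip was instead higher in reporter-high cells (ratios of 1.21 to 1.87), so the pooled Hhip ratio does not hold for these clusters. Sftpb, Sftpa1 and Lyz2 are abundant in alveolar epithelium or phagocytes, and these and the contractile genes Actg2, Actc1 and Myh11 fell below 1 in at least 1 alternative, such as 0.907 for Sftpb and 0.708 for Actg2 with doublets kept.

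The authors' deposited table of cluster comparisons holds 17 clusters and 20714 genes. By the rank correlation of mean counts across genes, 10 of its clusters were closest to mesenchymal clusters here, 4 of them adventitial-like, 4 alveolar-like, 1 smooth muscle-like and 1 mesothelial-like, 6 to epithelial clusters and 1 to an unnamed cluster (best Spearman correlations 0.865 to 0.987, across genes, which are not independent replicates). In the authors' deposited table, Gli1 had a log2 fold change above 0 past an adjusted p threshold of 0.05 in 4 clusters, which were the 4 closest to adventitial-like cells. The authors' deposited table gives log2 fold changes for Gli1 of 0.97 in cluster 2, 1.65 in cluster 3, 1.02 in cluster 7 and 1.24 in cluster 11. Cluster 7 of the authors' deposited table was led by Lamc3 (2.89), Adh7 (2.52) and Ptch1 (1.91). In the authors' deposited table, cluster 6 was led by the contractile genes Cnn1 (7.77), Actc1 (7.66) and Actg2 (7.65), with Hhip at 4.31, and was nearly as close to the peribronchial or myofibroblast-like cluster here (correlation 0.934 against 0.939). Cluster 15 of the authors' deposited table, closest to mesothelial-like cells, was led by Slurp1 (10.25), Upk3b (9.72) and Lrrn4 (9.61). Leading genes of further clusters in the authors' deposited table were, for cluster 1, the alveolar fibroblast gene Slc7a10 (4.33), Scube2 (3.88) and Scn3a (3.71), and, for cluster 10, Cxcl14 (2.60), Nt5dc2 (2.42) and Slc38a5 (2.21). In the authors' deposited table, Entpd2 (2.57), Ccl11 (2.56) and Mmp3 (2.52) led cluster 2, Gxylt2 (2.58), Cilp (2.40) and Scara5 (2.31) led cluster 3, and Ube2c (4.31), Adh7 (2.32) and Nbl1 (1.75) led cluster 11. Cluster 12 of the authors' deposited table, matched to shallow cluster 15 at 0.901, was led by the immunoglobulin genes Iglc1 (7.27), Iglc2 (7.21) and Igkc (7.18). Cluster 9 of the authors' deposited table, matched to alveolar-like cluster 2 at 0.874 and nearly as close to adventitial-like cluster 6 (0.870), was led by Gm26917 (4.68), Fam71a (4.49) and Myom1 (4.47), and its Gli1 mean count of 0.278 was the highest of all 17, with a log2 fold change of 1.55 that did not pass the threshold. The authors' p-values compare cells of 1 library and do not measure a spread between animals.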

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

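The tests in this part on reporter transcripts and on cluster 16 were all chosen after the values were seen. Signals were looked for in barcodes and clusters that the comparisons left out, and the levels listed next lay above what a count of 0 allows, which does not test where the RNA came from.

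The 1727 barcodes removed by the cell filter had a median of 32.0% mitochondrial UMIs and 797 UMIs. They held Gli1 at 12.7 CPM (29 UMIs, 8.49 to 18.2), Egfp at 476 CPM (1090 UMIs, 449 to 506) and TdTomato at 44.2 CPM (101 UMIs, 36.0 to 53.6). Unnamed cluster 20, which is led by proliferation genes such as Top2a and Mki67, had Gli1 at 8.05 CPM (9 UMIs, 3.68 to 15.3). Unnamed cluster 23, 38 cells led by heart muscle genes such as Tnni3 and Myl7, had Gli1 at 29.6 CPM (10 UMIs, 14.2 to 54.4), and 42.1% of its cells were reporter-high. Its highest marker list was that of adventitial fibroblasts (mean z-score 1.16, 9 of 10 markers detected). Only the leading heart muscle genes, which are not one of the 19 marker lists, kept it unnamed. Adventitial-like cells were alike, with Gli1 at 27.4 CPM and 46.9% reporter-high, so which cells gave the Gli1 UMIs cannot be told. Unnamed cluster 19 was not flagged, with Gli1 at 2.61 CPM (3 UMIs, 0.539 to 7.63).

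Adventitial-like cells without an Egfp UMI held little TdTomato, 7.88 CPM (6.21 to 9.86, 1114 cells) against 59.0 CPM (52.5 to 66.1, 990 cells) in such alveolar-like cells, a ratio of 0.134 (0.102 to 0.172). Mesothelial-like cells without an Egfp UMI were as low, at 8.24 CPM (6 UMIs, 3.02 to 17.9), so the pattern is not confined to adventitial-like cells, while peribronchial or myofibroblast-like cells had 81.4 CPM and smooth muscle-like cells 47.5 CPM. Fewer UMIs per cell are argued against, since these adventitial-like cells were the deeper ones, at a median of 8519.5 UMIs (8297 to 8765) against 4716 (4577 to 4872). A reporter locus less active by that ratio is argued against as well, since it would need alveolar-like reporter-high cells at 14978 CPM of Egfp to match adventitial-like cells at 2000 CPM, and 0 of 518 (up to 0.710%) reached that while 33.3% of adventitial-like cells passed 2000 CPM. Recombined cells whose Egfp was not caught could not be the whole cause, because TdTomato was 7.42-fold higher (4.35 to 13.4) than in reporter-high adventitial-like cells, but a mixture of such cells with unrecombined ones stays open. No biological explanation was tested, since the labels give 1 group.

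Alveolar type 1-like cluster 16 held reporter-high cells (17.8%), and cluster 17 of the same class held none among 107. Doublets with alveolar-like fibroblasts stay open: 8 of 10 alveolar fibroblast markers were over 2 times higher than in cluster 17, the count set for the test. Only 7 had a lower bound above 2, and high levels of some were known when the test was set. Limch1 could not reach the limit by admixture, at 1276 CPM in cluster 17 and 1634 CPM in alveolar-like cells, so the count cannot decide. All 10 markers were higher in cluster 16, Limch1 least at 1.14-fold (lower bound 1.05). The excess over cluster 17 was a median of 0.373 of the gap between cluster 17 and alveolar-like cells (0.265 to 0.517 over the 10 markers). The median doublet score was 0.130 in cluster 16, 0.0121 in cluster 17 and 0.0406 in all kept cells. Free RNA is argued against, since the summed markers were 3.51-fold higher (3.34 to 3.68) in cluster 16 than in cluster 17. No biological explanation was tested.

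Mesothelial-like cells of cluster 14 and cells of the Hhip-high cluster 11 were often reporter-high (40.9% of the mesothelial-like class and cluster 11 together, 37.1 to 44.9%, with 0 of 29 in mesothelial-like cluster 24, median Egfp 4873 CPM in the reporter-high cells) with little Gli1. The pattern is not confined to them: alveolar-like cluster 2 (36.2% reporter-high, Gli1 at 6.29 CPM) and smooth muscle-like cluster 13 (29.4%, 6.19 CPM) were alike. The tests below did not cover those clusters. Free Egfp RNA is argued against by the 0.0615% of alveolar type 2-like cells (0.00156 to 0.342%) that were reporter-high. The share was higher in leukocyte-like cells, at 6.59% (2.46 to 13.8%), but still below the lower bound of 37.1% in the mesothelial-like class and cluster 11 together. Doublets with adventitial-like cells are argued against too, since adventitial markers in reporter-high over reporter-low cells were at 0.940 (0.893 to 0.989) in cluster 14 and 1.01 (0.955 to 1.07) in cluster 11, where 2.59 and 3.02 would be needed, while a first form that pooled both classes gave 0.596 (0.577 to 0.616) and mixed cells of different makeup. For too few UMIs, Gli1 was 5.16 CPM (8 UMIs, 2.23 to 10.2), 0.186-fold (0.080 to 0.371) that of reporter-high adventitial-like cells. This comparison cannot decide, because low Gli1 in these clusters is what defined the pattern. A candidate explanation is Gli1 expression at dosing that had ceased by harvest, or recombination without Gli1 expression, and neither was tested, because the labels give no other group. Both take Gli1 to be absent at harvest, which the counts do not show. Its lower bound of 2.23 CPM lay above the 0.0640 CPM of alveolar type 2-like cells, and whether the UMIs came from these cells was not tested.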

How the results depend on the processing

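Of 22 alternatives, 14 were planned and 8 were chosen after seeing the data, and no result here comes from a test. The 21 main results gave 263 values under them, of which 226 stayed within counting error or 1.5 times for counts, 35 moved and 2 reversed. The 326 other results gave 3823 values, with 3056 unchanged in that sense, 723 moved and 44 reversed, and 262 of 2240 ratios moved by over 1.5 times. The cause was not tested for any change below except where fewer UMIs or another limit by construction change a share. Reporter Gli1 stayed between 0.95 and 1.06, and adventitial-like over alveolar-like counts ran from 54 to 72 genes at 2 or more and 23 to 32 at 0.5 or less. For the other classes these counts were 32 to 37 and 106 to 116 (mesothelial-like), 33 to 41 and 84 to 93 (peribronchial or myofibroblast-like) and 27 to 32 and 85 to 117 (smooth muscle-like, a class not found with the naming rule as first written). No paired analysis was possible because the labels give 1 group and no file maps cells to samples, and leaving out each replicate was not run for the same reason. Depth limits Gli1, which had 1047 UMIs in kept cells.

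The mesenchymal share of 72.1% was 66.7% with 4000 variable genes, 63.8% at resolution 0.5, 68.4% at resolution 2.0, 59.1% with UMIs split in separate parts, 65.2% without cluster 6, 70.3% without cluster 15, 64.8% with doublets kept, 57.2% with the looser filter, 69.7% with the first naming rule, 70.2% with another seed and 75.1% with the stricter filter. The share of named classes that the sort should remove, leukocyte-like cells alone in the main run, was 1.02%. It was 1.67% with split UMIs, 1.91% with the looser and 0.715% with the stricter filter. The main value leaves out unnamed cluster 22, with endothelial and haemoglobin genes, which held 61 cells (0.683%). Clusters numbered 38 rather than 25 at resolution 2.0.

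The adventitial-like Gli1 ratio of 5.06 was 2.73 at resolution 2.0, 3.73 with doublets kept and 3.69 with the stricter filter, and the thinned share of 5.24% was 2.75% at 1000 and 9.84% at 4000 UMIs. The hedgehog count of 5 was 3 at resolution 2.0. Gas1, at 1.03, was 0.923 with 4000 variable genes, 0.981 at resolution 0.5, 0.892 at resolution 2.0, 0.802 with split UMIs, 0.954 without cluster 6, 0.959 with doublets kept, 0.849 with the looser filter, 0.95 with the first naming rule and 0.853 with the stricter filter. Smooth muscle-like Hhip, at 0.0596, was 6.70 with 4000 variable genes, 1.72 at resolution 2.0, 4.82 with split UMIs, 6.33 with doublets kept and 6.25 with the looser filter. Peribronchial or myofibroblast-like Cnn1 was 0.520 at resolution 2.0, and Myh11 in adventitial-like cluster 4 was 0.976 with the stricter filter.

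In matched cells, Hhip (1.17) was 1.26 in adventitial-like cells only, 0.689 unmatched, 0.944 with 2 or more Gli1 UMIs, 1.10 with doublets kept and 1.25 with the stricter filter. Ptch1 (1.18) was 1.45 unmatched and 1.02 with 2 or more Gli1 UMIs. With 2 or more Gli1 UMIs, Ccl2 was 1.81, Slpi 1.40, Upk3b 4.89 and Tbx2 1.25. With 1 matched cell, Egr3 was 0.966, Slpi 1.47 and Tbx2 1.08. In adventitial-like cells only, Tagln was 1.12, Tpm2 1.01 and Upk3b 4.26.

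The adventitial-like reporter-high share of 46.9% was 44.0% at resolution 0.5, 49.9% with the looser filter, 33.3% from 2000 CPM and 54.6% from 500 CPM. The alveolar-like share of 28.2% was 35.6% at resolution 2.0, 23.8% from 2000 CPM, 30.5% from 500 CPM and 31.8% with the stricter filter. In reporter-high against reporter-low cells, with 4000 variable genes, resolution 2.0, doublets kept and the looser filter in turn, Actc1 was 0.574, 0.871, 0.495 and 0.770, Actg2 was 0.706, 0.766, 0.708 and 0.735, and Myh11 was 0.772, 0.959, 0.756 and 0.777. Hhip was 1.02 with doublets kept and 1.02 with the looser filter, where Ptch1 was 1.38. Lyz2 was 0.769 with doublets kept and 0.941 from 500 CPM, and with doublets kept Sftpa1 was 0.876 and Sftpb 0.907.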

Other observations

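The comparisons in this part were all chosen after the data were examined. The adventitial-like fibroblasts were not uniform, and each of their 6 clusters was set against the other adventitial-like cells. Cluster 3, with the most reporter-high cells, had high levels of the Wnt inhibitor genes Notum (80.8-fold, 61.1 to 109) and Wif1 (69.5-fold), the growth factor gene Bmp7 (74.6-fold), Ltbp2 (23.4-fold), the retinol esterifying enzyme gene Lrat (11.6-fold) and Tnc (8.13-fold). It had low Aldh1a2 (0.0125, 5 UMIs), Fst (0.0269) and Ccl7 (0.0277), and Ptch1 at 388 CPM and Hhip at 340 CPM, against 166 and 105 CPM in the other adventitial-like cells. Cluster 5 had high Col8a1 (22.2-fold), the elastin gene Eln (3.30-fold), Lmod1 (3.19-fold), Sdc1 (2.74-fold), Lum (2.56-fold) and Col15a1 (2.21-fold). Cluster 6 had Alcam (6.66-fold), Bmp3 (6.65-fold), Fmod (4.67-fold), Itga8 (4.24-fold), the growth factor gene Hgf (4.22-fold) and the chemokine gene Cxcl14 (3.97-fold). With 4000 variable genes Notum in cluster 3 was 131-fold, and Col8a1 in cluster 5 was 7.47-fold.

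Cluster 8 had high Aldh1a2 (4.63-fold), Podn (3.56-fold), Wnt2b (3.14-fold), Fabp4 (3.03-fold), the Wnt enhancer gene Rspo3 (3.02-fold) and Rspo1 (2.69-fold). Cluster 9, with the fewest reporter-high cells of the class, had Fgf18 (8.69-fold), Thy1 (6.90-fold), Rspo3 (5.80-fold), the chemokine gene Ccl7 (4.65-fold), Fabp4 (4.54-fold) and the lipoprotein lipase gene Lpl (4.19-fold), with Ptch1 at 56.4 CPM. Cluster 4 stood apart least, with Lepr at 2.19-fold, Cxcl12 at 1.62-fold, Myh11 at 1.62-fold (33 UMIs, but 0.976 with the stricter filter) and C4b at 1.58-fold. At resolution 2.0, Thy1 in cluster 9 was at 1.20 and Fgf18 at 2.15.

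Reporter-high and reporter-low adventitial-like cells lay in different proportions in the 6 clusters, so they were compared within each cluster. In each of them the interval of the Gli1 ratio of reporter-high over reporter-low cells included 1. The Ptch1 ratio was 1.19 in cluster 3 (1.06 to 1.34), 1.25 in cluster 4, 1.31 in cluster 5 and 1.27 in cluster 6, with intervals above 1, and 1.13 in cluster 8 and 1.06 in cluster 9, with intervals that included 1. The Hhip ratio was 1.25 in cluster 3 (1.10 to 1.42), 1.87 in cluster 4 (1.60 to 2.19), 1.21 in cluster 5 (1.04 to 1.42) and 1.37 in cluster 8 (1.16 to 1.62). It was 1.16 in cluster 6 (0.862 to 1.57) and 0.482 in cluster 9 (0.281 to 0.791). Xist, the X-inactivation transcript, had a UMI in 93.1% of kept cells (8315), and Y-linked genes had a UMI in 3 cells.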
